A study of Mus musculus with 15 samples.

How the data were processed

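Total RNA from N2a mouse neuroblastoma cells was sequenced in 15 libraries, 3 in each of 5 groups, taken on day 3 after siRNA (50 nM) and plasmid were delivered together. Groups were taken from the sample labels. RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit, per the labels' protocols. Per the submitters' processing notes, fastp, HISAT2, HTSeq and R 3.2.0 were used with the mouse build GRCm39; the versions of the first 3 tools, the annotation, the strand setting and any filters are not stated. The deposited table holds raw counts and deposited FPKM for 22507 genes in each library. Counts were whole numbers that summed to 20070123 to 27809960 per library. FPKM was checked against the counts and was equal to counts divided by gene length and by the table's own total, with a largest relative gap of 1.1e-06. No gene in the table was at 0 in every library (0 of 22507).

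The counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Normalization was TMM, low counts were removed with filterByExpr, which left 13074 genes, and a quasi-likelihood model with 1 mean per group was fitted to all 15 libraries (10 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over the genes tested in a comparison, and genes were called at an adjusted p under 0.05. The design named this test for a table with counts, and limma-trend on FPKM for a table without them. The 7 comparisons were knockdown against control, wild-type OPA1 against knockdown, each mutant against wild type, V465F against V560F, and each mutant against knockdown. The median coefficient of biological variation was 8.22%, and the median half-width of the 95% interval of a log2 fold change was 0.217 to 0.228 among the comparisons. On simulated data with 50 genes changed at each size, 72 to 90% of 1.5-fold changes and 90 to 98% of 2-fold changes were recovered, and 1.32 to 7.14% of calls were false.

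The comparisons, tests, thresholds, 39 gene lists and the rule for naming genes were chosen before the data were examined. Lists were tested with camera with a preset inter-gene correlation of 0.01, with camera with an estimated correlation and with fry, and p-values were adjusted over the 39 lists of a comparison. In the order of the comparisons, camera with the preset correlation called 16, 16, 21, 22, 10, 21 and 20 lists, and fry, which tests each list by itself, called 18, 3, 30, 28, 2, 35 and 31. The lists printed in the report are those with a bearing on mitochondria, cell death and the neuronal line, and those with the lowest camera adjusted p, and this choice was made after the values were seen; for the remaining lists only their numbers are given. The naming rule took Opa1, then the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 1 FPKM and values that did not overlap between the groups, then up to 4 called members with the lowest adjusted p of each list, or 2 members where none was called. For 3 libraries against 3, chance separates 10% of genes in this way. The report prints some of these genes and not others, and some that the rule names are withheld and not reported here. Slc18a2, Hexa, Ddit3 and Pyy in the wild-type comparison and the genes of gene ontology terms in the closing section fall outside the rule, and they, with Ucp2 and Acot2 from among the genes it names, were chosen after their values were seen.

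A correction for each library's trend with transcript length and GC content used a spline with 5 degrees of freedom. Length came from the FPKM and GC content from GENCODE release M21, matched by Entrez gene ID, or by symbol where that gave no value. This gave a value for 12510 of the 13074 tested genes (95.7%). That release is on an older mouse build than the deposited table, so it was used only for GC content and for gene overlaps, and no coordinates are given. Overlaps are marked beside some named genes only. Among the unmarked, Junb, Irf1, Irf3, Twnk, Hexa, Lamp1, Grn and Sqstm1 also overlap a gene on the opposite strand, and Fdft1 and Ctsb overlap each other. Alternatives planned in advance were limma-trend on FPKM with pseudocounts of 0.1 and 0.5, with median-ratio scaling and with quantile normalization, no filter, a filter of 5 FPKM in 3 libraries, only the 6 libraries compared, a replicate block, robust moderation, array weights, DESeq2 size factors, DESeq2 1.42.0, each library left out in turn, and an estimated inter-gene correlation. The median-ratio and quantile fits used a pseudocount of 1. Further alternatives were chosen after the data were seen. These were limma-trend with a pseudocount of 1, the length and GC correction, only genes with both values, the 2 libraries farthest from their groups left out, the 50 most abundant genes left out, and all libraries thinned to the smallest total. Overlaps between comparisons with shared libraries were set beside 100 simulated draws of unchanged groups. Gene ontology terms of 15 to 300 genes (2095 terms) were tested with camera.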

Results

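RNA was sequenced from N2a cells, a mouse neuroblastoma line, 3 days after siRNA at 50 nM and a plasmid were delivered together. OPA1 is a dynamin-like GTPase of the inner mitochondrial membrane that acts in membrane fusion and cristae shape, and its mutations cause dominant optic atrophy. The 15 libraries fell into 5 groups of 3. The control group received control siRNA and control plasmid, and the knockdown group received siRNA against Opa1 with the control plasmid. The remaining groups received the siRNA against Opa1 with a plasmid encoding OPA1, either wild type or carrying the V560F or the V465F substitution. Deposited gene counts totalled 20070123 to 27809960 per library, and 13074 of 22507 genes had enough counts to be tested. Log2 fold changes are given with their standard errors from the edgeR quasi-likelihood fit with n = 3 libraries per group. Levels are CPM (counts scaled to library size by TMM) as mean ± SD, and the median gene had a standard error of 0.105 to 0.110 on the log2 scale. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

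The targeted gene was read first in every library. Opa1 (Entrez gene 74143) stood at 95.9 ± 4.94 CPM in the control libraries (n = 3) and at 36.8 ± 2.52 CPM in the knockdown libraries (n = 3), which is 38.4% of control. Its log2 fold change was -1.38 ± 0.0834 (edgeR adjusted p = 8.53e-10). The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it allows. Opa1 stayed low in every group that received the siRNA, at 31.4 ± 2.27 CPM with wild-type OPA1, 32.0 ± 4.28 CPM with V560F and 33.9 ± 0.723 CPM with V465F. Opa1 was not called by edgeR in either mutant group against the wild-type group (log2 fold change 0.03 ± 0.0879, edgeR adjusted p = 0.818 for V560F, and 0.11 ± 0.0871, edgeR adjusted p = 0.333 for V465F). The labels do not give the species or coding sequence of the plasmid insert, so whether RNA from the plasmid was counted as mouse Opa1 is not known. These counts do not measure its expression.

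**Figure D1:**
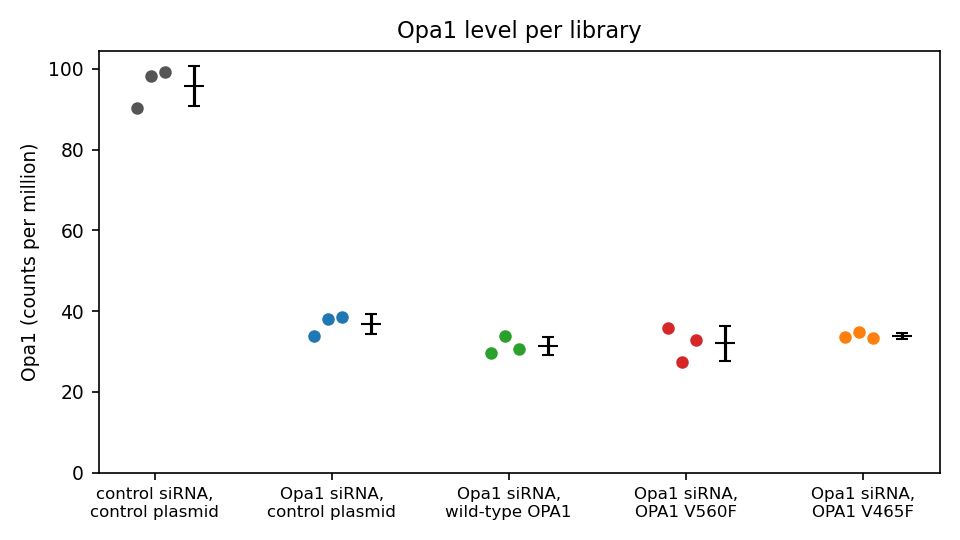
Opa1 CPM in each of the 15 libraries (points), with the mean and SD of each group of 3 (black bars). The control libraries lie between 90.2 and 99.2 CPM, and the 12 libraries that received siRNA against Opa1 lie between 27.3 and 38.5 CPM.

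Across all tested genes, the group means lay in an order along the first principal component, which held 56.4% of the variance. The control libraries had a mean score of -49.4, the knockdown libraries -14.1, the wild-type libraries -8.36, the V465F libraries 30.6 and the V560F libraries 41.2. Single libraries of knockdown (-15.46 to -11.53) overlapped those of wild type (-15.25 to 0.0184). Those of V465F (25.84 to 35.76) overlapped those of V560F (34.23 to 51.92), so these steps were not separated. A trend with transcript length ran along the same order of means. The slope of log2 level on log10 transcript length, relative to the mean of all libraries, was 0.42 ± 0.0909 in control, 0.21 ± 0.00862 in knockdown, 0.10 ± 0.151 in wild type, -0.25 ± 0.0465 in V465F and -0.48 ± 0.293 in V560F (mean ± SD, n = 3 each). V560F replicate 2, at -0.82, and wild-type replicate 3, at -0.07, stood apart from their groups. The 50 genes with the most counts took 18.04% of counts in control and 23.3% in V560F. Values corrected for each library's trend with length and GC content are therefore given beside the gene groups that move with it. Fold changes also rose with expression level (Spearman rho 0.416 in the knockdown, 0.236 for V560F and 0.229 for V465F against wild type). The correction does not model that trend with level, and its part in the gene lists was not tested.

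**Figure D2:**
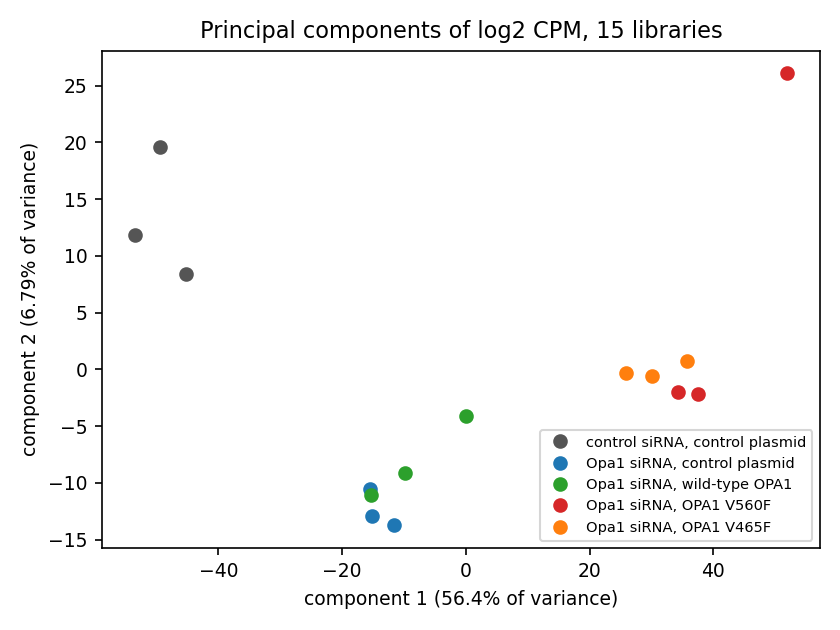
Principal components of log2 CPM over the tested genes, with 1 point per library, coloured by group. Component 1 (56.4% of the variance) runs from a mean of -49.4 in control to 41.2 in V560F, and component 2 holds 6.79%.

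**Figure D3:**
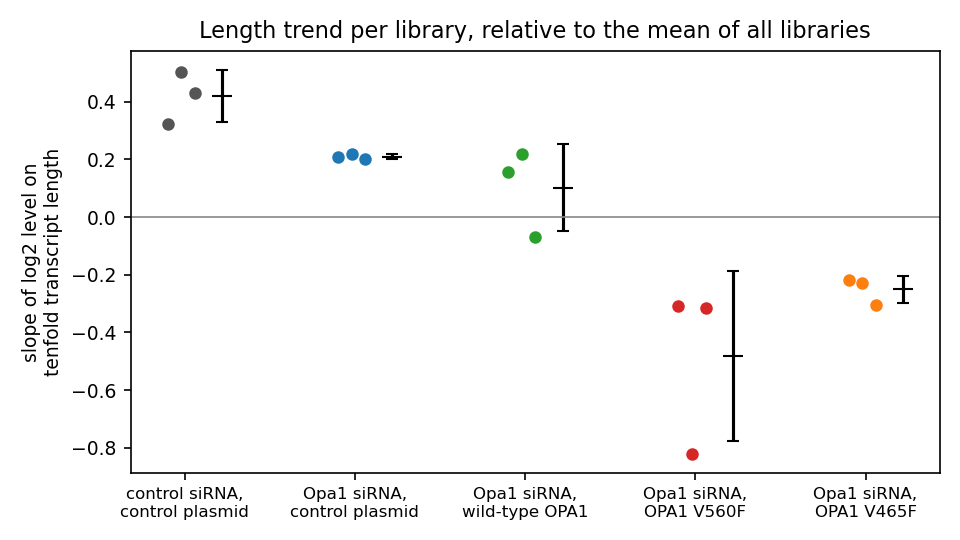
Slope of log2 level on log10 transcript length in each library, relative to the mean of all 15 libraries, with the mean and SD of each group of 3. Slopes run from 0.505 in a control library to -0.82 in V560F replicate 2.

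The first comparison, knockdown against control, asks what siRNA against Opa1 changed in the transcriptome of these cells. Whether the changes come from the loss of Opa1 itself was not tested. Most measured genes of lysosomes and cytosolic ribosomal proteins rose, and of genes of DNA replication and of the endoplasmic reticulum and integrated stress responses more rose than fell. Of genes of sympathetic neuroblast identity and of nucleic acid sensing, more fell than rose. Among lysosomal genes, 27 of 33 measured rose and 1 fell (27 and 1 adjusted over the list alone), with a median log2 fold change of 0.34 (camera adjusted p = 3.94e-10, adjusted p = 0.133 with an estimated correlation). Hexa, a subunit of hexosaminidase, rose by 0.51 ± 0.0592 and the progranulin gene Grn by 0.54 ± 0.0745 (edgeR adjusted p = 3.85e-06 and 2.36e-05). The lysosomal membrane genes Lamp1 and Lamp2 rose by 0.43 ± 0.0605 and 0.52 ± 0.0628 (edgeR adjusted p = 2.60e-05 and 5.91e-06). Sqstm1, an autophagy receptor, went from 726 ± 33.8 to 1088 ± 28.1 CPM. In its list of mitophagy and autophagy genes 14 of 38 rose and 3 fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.0133, adjusted p = 0.356 with an estimated correlation).

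Of the stress-response genes, more rose than fell with the knockdown. Ddit3, which encodes the stress transcription factor CHOP and overlaps a gene on the other strand, went from 118 ± 12.1 to 203 ± 5.67 CPM (log2 fold change 0.78 ± 0.0968, edgeR adjusted p = 7.31e-06). Of the 40 measured targets of the integrated stress response, 22 rose, among them Phgdh (0.52 ± 0.0710) and Cebpb (0.55 ± 0.0934), and 3 fell, with the same numbers adjusted over the list alone (camera adjusted p = 5.74e-05, adjusted p = 0.482 with an estimated correlation). In the unfolded protein response of the endoplasmic reticulum, 14 of 27 genes rose and 1 fell (15 and 1 adjusted over the list alone), led by the chaperone genes Hspa5 (0.59 ± 0.0760) and Calr (0.52 ± 0.0675) (camera adjusted p = 4.31e-06, adjusted p = 0.304 with an estimated correlation). DNA replication genes rose in 19 of 37 cases (23 adjusted over the list alone), including Cdt1 (0.64 ± 0.0615) and Mcm3 (0.50 ± 0.0735). G2 and M phase genes rose in 20 of 37 (21 adjusted over the list alone), including Top2a (0.50 ± 0.0671). None in either list fell, by the edgeR test (camera adjusted p = 4.31e-06 and 2.45e-05, adjusted p = 0.204 and 0.304 with an estimated correlation). Of 34 Myc targets, 20 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 0.000191, adjusted p = 0.482 with an estimated correlation).

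Genes of the cytosolic ribosome and, in part, of the respiratory chain and the mitochondrial ribosome also rose. Among cytosolic ribosomal protein genes, 68 of 74 rose (70 adjusted over the list alone) with a median log2 fold change of 0.32, which was 0.18 with 54 called after correction for length and GC content (camera adjusted p = 5.15e-12, adjusted p = 0.686 with an estimated correlation). Nuclear genes of respiratory complexes II to V rose in 30 of 39 cases (33 adjusted over the list alone; median 0.28, corrected 0.18), such as Atp5b (0.38 ± 0.0684). Those of complex I rose in 18 of 37 (19 adjusted over the list alone; median 0.23, corrected 0.09). Their camera adjusted p-values were 3.89e-07 and 0.000388 (adjusted p = 0.686 for both with an estimated correlation), and complex I was no longer called after the correction (camera adjusted p = 0.479). Mitochondrial ribosomal protein genes had 25 of 77 higher and 3 lower (29 and 5 adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.686 with an estimated correlation), and their call was also lost after the correction (camera adjusted p = 0.429).

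Some genes of the sympathetic lineage fell after knockdown. The vesicular monoamine transporter gene Slc18a2 fell from 188 ± 7.81 to 125.5 ± 6.71 CPM. Dbh, which makes noradrenaline, fell by 0.86 ± 0.177 on the log2 scale (edgeR adjusted p = 2.92e-06 for Slc18a2 and 0.000883 for Dbh). Of the 19 genes in that list, 7 fell and 2 rose, with the same numbers adjusted over the list alone (camera adjusted p = 0.0280, adjusted p = 0.304 with an estimated correlation; 0.0783 after the length and GC correction). Among 10 genes of cytosolic nucleic acid sensing 3 fell, Eif2ak2 (-0.74 ± 0.0878), Irf3 (-0.82 ± 0.151) and Adar (-0.39 ± 0.0894), again 3 adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.236 with an estimated correlation). Genes of mitochondrial fusion, fission and cristae shape went both ways, with 7 of 36 higher and 5 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.944). Beside Opa1, the outer membrane protein gene Slc25a46 fell by 0.62 ± 0.0944 and the cristae gene Chchd3 rose by 0.32 ± 0.0731. Pro-apoptotic genes were also mixed, with 4 of 24 higher and 6 lower (4 and 6 adjusted over the list alone; camera adjusted p = 0.486). In that list Bak1 rose by 0.58 ± 0.0989, while Fadd and Bmf fell by 1.16 ± 0.250 and 0.65 ± 0.108.

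In all, 4689 of the 13074 genes changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 2599 up and 2090 down, and of these 40 rose and 369 fell by at least 2-fold. These 409 were 26 on FPKM with a pseudocount of 1, and with that pseudocount 18 after median-ratio scaling and 16 after quantile normalization. They were 23 in the edgeR test with a filter of 5 FPKM. Among the largest falls were those of Tpbgl (4.31-fold, from 20.5 ± 3.23 to 4.74 ± 2.15 CPM), Nags (3.25-fold), which encodes N-acetylglutamate synthase, and the glycosyltransferase gene A4galt (2.85-fold). Others were those of the imprinted non-coding gene Peg13 (2.67-fold), Opa1 itself, and the neighbouring peptide hormone genes Pyy (2.58-fold) and Ppy (2.44-fold, from 58.2 ± 2.88 to 23.8 ± 3.75 CPM). Among the largest rises were those of genes of low level such as the metallothionein gene Mt1 (3.25-fold, from 0.328 ± 0.171 to 1.10 ± 0.409 CPM), Spp1 (2.86-fold), Gja6 (2.39-fold) and Akr1b7 (2.02-fold). Tpbgl, Nags and Akr1b7 overlap a gene on the other strand, and Spp1 overlaps one on its own strand. On the deposited FPKM scale, where values are divided by the table total, the split was 1039 up and 2940 down, and after the length and GC correction it was 3762 up and 1702 down. The balance of directions thus depended on the scaling. Of the 39 gene lists, 16 were called with the preset correlation and 0 with an estimated one.

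The second comparison, wild-type OPA1 against control plasmid in Opa1-depleted cells, asks what the wild-type plasmid changed. No gene passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, where the smallest adjusted p was 0.363, while 1157 of 13074 genes had an unadjusted p under 0.05. DESeq2 called 5 genes and limma on FPKM 0, while 40 were called by edgeR with no filter on low counts, 3 by edgeR with only the 6 libraries, 2 by edgeR without the 2 libraries farthest from their groups and 43 with array weights. Opa1 itself was at 31.4 ± 2.27 against 36.8 ± 2.52 CPM (log2 fold change -0.23 ± 0.0855, edgeR adjusted p = 0.522). Of genes called in the knockdown, Slc18a2, Hexa, Ddit3 and Pyy were at 0.11, 0.14, 0.17 and -0.09 on the log2 scale (edgeR adjusted p = 0.649, 0.537, 0.618 and 0.846). Ucp2, which overlaps a gene on the other strand, and Acot2 lay further from 0, at 0.38 ± 0.0843 and -0.48 ± 0.170 (edgeR adjusted p = 0.363 and 0.502), against -0.50 ± 0.0843 and 0.63 ± 0.172 in the knockdown. With no filter, only the 6 libraries, the farthest libraries left out and array weights, Ucp2 was called at adjusted p = 0.0013, 0.0374, 0.0237 and 0.0189. Without control replicate 2 that rise of Acot2 was 0.48 (edgeR adjusted p = 0.0596). Both comparisons use the knockdown libraries, which by itself favours opposite signs. Ucp2 and Acot2 were chosen after their values were seen and do not stand for all genes. Across all genes the covariance of the 2 comparisons was -0.0183, against -0.0243 to -0.0202 in simulated unchanged groups that share those libraries. The genes as a whole were thus not more opposed than in those simulations. Of 24 cholesterol biosynthesis genes none was called over all genes, while 4 rose adjusted over the list alone, with a median log2 fold change of 0.12 (camera adjusted p = 3.47e-07, adjusted p = 0.333 with an estimated correlation). Lss and Hsd17b7, both enzymes of the pathway, were at 0.25 and 0.24 (edgeR adjusted p = 0.367 and 0.392). Of 32 interferon response genes none was called over all genes and 5 rose adjusted over the list alone, with a median of 0.19 (camera adjusted p = 1.83e-05, adjusted p = 0.116 with an estimated correlation). The interferon-induced genes Oasl2 and Cxcl10 were at 0.78 and 0.68 (edgeR adjusted p = 0.363 for both). Of the 39 lists, 16 were called with the preset correlation, 15 upward, and 0 with an estimated one. In simulated data 17 of 50 genes with 1 group 25% above the other, 36 of 50 changed by 1.5-fold and 46 of 50 changed by 2-fold were recovered in this comparison. The median gene had a 95% interval of ±0.218 on the log2 scale.

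The third comparison sets V560F against wild-type OPA1 in Opa1-depleted cells. The NF-kB inhibitor gene Nfkbia was higher with the mutant, immediate early, ribosomal, respiratory chain and cell cycle genes were higher on balance, and of axon guidance, sympathetic lineage and nucleic acid sensing genes more fell than rose. The transcription factor gene Fos went from 9.34 ± 0.425 to 27.0 ± 2.66 CPM (2.89-fold). Egr1 went from 73.2 ± 2.47 to 162.9 ± 8.99 CPM (2.23-fold) and Junb from 27.9 ± 1.55 to 61.2 ± 10.99 CPM (2.20-fold), with edgeR adjusted p = 4.12e-08 for Fos, 3.47e-09 and 1.61e-07. Nfkbia, which encodes the NF-kB inhibitor IkBa, rose 2.36-fold to 239.7 ± 32.9 CPM, the chemokine gene Cxcl1 3.04-fold to 6.92 ± 0.394 CPM, and Irf1 1.84-fold (edgeR adjusted p = 3.44e-09, 1.16e-05 and 2.98e-08). Of 30 immediate early genes, 17 rose and 0 fell by the edgeR test (17 and 0 adjusted over the list alone), with a median log2 fold change of 0.42 as deposited and 0.49 after the length and GC correction (camera adjusted p = 4.10e-06, adjusted p = 0.308 with an estimated correlation). NF-kB target genes as a list went both ways, with 9 of 19 higher and 5 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.147).

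**Figure D4:**
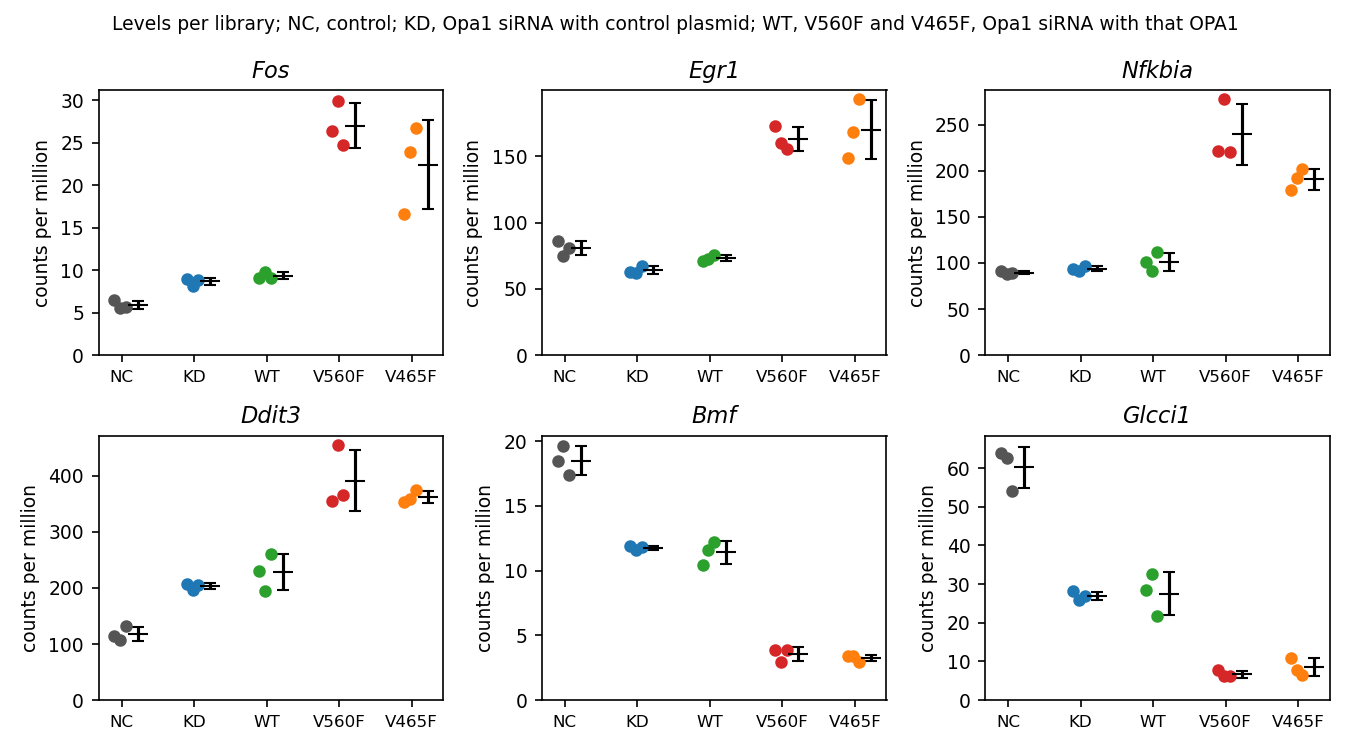
CPM of 6 genes in each of the 15 libraries (points), with the mean and SD of each group of 3; NC is control, KD knockdown, and WT, V560F and V465F the groups with that OPA1. Fos lies at 9.34 ± 0.425 CPM in wild type, 27.0 ± 2.66 in V560F and 22.4 ± 5.23 in V465F, and Bmf at 11.4 ± 0.876, 3.54 ± 0.541 and 3.25 ± 0.232.

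All 74 measured cytosolic ribosomal protein genes rose with V560F, and 74 did so adjusted over the list alone, with a median log2 fold change of 0.71 that was 0.32 with 68 called after the length and GC correction (camera adjusted p = 8.55e-38, adjusted p = 0.308 with an estimated correlation). Respiratory complex I genes rose in 36 of 37 cases and genes of complexes II to V in 37 of 39, both the same adjusted over the list alone. Their medians of 0.53 and 0.60 fell to 0.12 and 0.14 after the correction, where 17 and 20 were called (camera adjusted p = 4.66e-13 and 2.35e-16, adjusted p = 0.335 for both with an estimated correlation). Ndufb11 rose by 0.74 ± 0.0936 (0.37 corrected) and Atp5g2, a subunit of the ATP synthase, by 0.76 ± 0.0823 (0.33 corrected). Mitochondrial ribosomal protein genes rose in 59 of 77 cases (61 up and 1 down adjusted over the list alone), with a median of 0.37 as deposited and 0.15 corrected (camera adjusted p = 6.47e-11, adjusted p = 0.351 with an estimated correlation). Of the 13 proteins encoded by mitochondrial DNA, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.427). COX1 went from 42550 ± 1488 to 61150 ± 1621 CPM, and after the correction 10 of the 13 were lower and 1 higher (camera adjusted p = 0.000129, adjusted p = 0.276 with an estimated correlation). Twnk, which encodes a helicase of mitochondrial DNA, fell by 0.98 ± 0.127. In its list of mitochondrial DNA maintenance and biogenesis genes 4 of 22 were higher and 9 lower (4 and 10 adjusted over the list alone, camera adjusted p = 0.218).

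Of cell cycle and stress genes, more rose than fell with V560F. G2 and M phase genes were higher in 29 of 37 cases (29 adjusted over the list alone; median 0.30, corrected 0.29), with Top2a at 0.69 ± 0.0672 and the cyclin gene Ccna2 at 0.62 ± 0.0580 (camera adjusted p = 2.53e-09, adjusted p = 0.233 with an estimated correlation). DNA replication genes were higher in 24 of 37 and lower in 3 (24 and 3 adjusted over the list alone), with Mcm3 at 0.73 ± 0.0728 (camera adjusted p = 7.05e-06, adjusted p = 0.233 with an estimated correlation). The linker histone gene H1f2 rose 2.85-fold, from 27.6 ± 2.85 to 78.5 ± 15.2 CPM. Histone genes are near-identical copies of each other, so how reads were shared among them is uncertain. Of 40 integrated stress response genes, 25 rose and 6 fell (26 and 10 adjusted over the list alone), with Ddit3 at 0.78 ± 0.0958 and Ppp1r15a, which encodes a phosphatase subunit of that response, at 0.73 ± 0.0895 (camera adjusted p = 0.0008, adjusted p = 0.404 with an estimated correlation; median reversed to -0.0575, adjusted p = 0.884, with quantile normalization). Cholesterol biosynthesis genes rose in 12 of 24 cases and fell in 2 (13 and 2 adjusted over the list alone), among them Fdft1 (0.47 ± 0.0642) and Nsdhl (0.49 ± 0.0644) (camera adjusted p = 0.00204, adjusted p = 0.404 with an estimated correlation; median reversed to -0.118, adjusted p = 0.0671, with quantile normalization). Lysosomal genes rose in 18 of 33 and fell in 3 (18 and 4 adjusted over the list alone), with Ctsb at 0.48 ± 0.0693 (camera adjusted p = 0.0008, adjusted p = 0.308 with an estimated correlation; median reversed to -0.039, adjusted p = 0.884, with quantile normalization).

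Some genes that guide axons and mark sympathetic neuroblasts fell with V560F. The semaphorin genes Sema6a and Sema6d fell 2.92-fold and 2.59-fold, to 7.80 ± 2.38 and 11.1 ± 2.45 CPM (edgeR adjusted p = 1.13e-07 and 2.61e-07). The netrin receptor gene Unc5c fell by 1.05 ± 0.121 and the ephrin gene Efna5 by 0.69 ± 0.0789 on the log2 scale (edgeR adjusted p = 8.78e-07 and 8.27e-07). Of 31 axon guidance genes, 13 fell and 1 rose (13 and 1 adjusted over the list alone). This list holds long transcripts, with a median of 7692 nt, and its median of -0.38 became -0.11, with 7 down and 6 up, after the length and GC correction (camera adjusted p = 0.000501, adjusted p = 0.335 with an estimated correlation; 0.0458 after the length and GC correction). The lineage regulator Gata2 fell by 0.57 ± 0.0797. Of 19 sympathetic identity genes 8 fell and 0 rose by the edgeR test (8 and 0 adjusted over the list alone; camera adjusted p = 0.0407, adjusted p = 0.308 with an estimated correlation, and 0.0511 after the length and GC correction). Among 10 nucleic acid sensing genes, 6 fell and 1 rose (6 and 1 adjusted over the list alone), with the RNA-editing enzyme gene Adar at -1.04 ± 0.0980, Eif2ak2 at -0.76 ± 0.0962 and Ddx58, the RNA sensor RIG-I, at -0.55 ± 0.102 (camera adjusted p = 0.0356, adjusted p = 0.308 with an estimated correlation). Adar and Eif2ak2 overlap other genes on the opposite strand.

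Cell death genes went both ways. Bmf, a BH3-only pro-apoptotic gene, fell 3.22-fold from 11.4 ± 0.876 to 3.54 ± 0.541 CPM (log2 fold change -1.69 ± 0.131, edgeR adjusted p = 9.89e-09). Bbc3, which encodes PUMA, rose by 0.62 ± 0.0997 and the survivin gene Birc5 by 0.61 ± 0.0790. Of 24 pro-apoptotic genes 6 rose and 4 fell, and of 14 anti-apoptotic genes 5 rose and 3 fell, with the same numbers adjusted over each list alone (camera adjusted p = 0.950 and 0.618). Genes of mitochondrial fusion, fission and cristae shape were also mixed, with 14 of 36 higher and 7 lower (14 and 7 adjusted over the list alone; camera adjusted p = 0.107). The fusion gene Mfn2 fell by 0.57 ± 0.0726 (0.30 after the correction) and the fission adaptor gene Mief1 by 0.52 ± 0.0828, while Chchd3 rose by 0.53 ± 0.0728. Markers of mesenchymal or Schwann-like cells, of leukocytes and of epithelial cells were called in 0 of these 3 lists by camera (adjusted p = 0.0512, 0.370 and 0.189). In them 2, 1 and 0 of their 17, 4 and 5 measured genes rose while 6, 0 and 2 fell, with the same numbers adjusted over each list alone.

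In all, 6464 genes changed (edgeR adjusted p under 0.05), 3204 up and 3260 down, of which 124 rose and 435 fell by at least 2-fold. These 559 were 78, 30, 28 and 115 in the same 4 settings, and 323 after the length and GC correction. The largest named falls, beside Bmf, included Zfp455 (4.33-fold), Cyp2u1 (4.13-fold), Ccnjl (4.10-fold), Glcci1 (4.09-fold, from 27.6 ± 5.48 to 6.74 ± 0.882 CPM), Fbxl7 (3.44-fold) and Manea (3.31-fold). Glcci1 overlaps other genes on both strands, and Cyp2u1 and Ccnjl each overlap one on the opposite strand. Hk2, the hexokinase bound to mitochondria, fell 2.12-fold to 27.9 ± 1.85 CPM. The largest named rises, beside Fos, Cxcl1 and H1f2, included Lncpint (2.77-fold, overlapped on the opposite strand) and Kcns3, whose 15.7 ± 11.9 CPM rested on V560F replicate 2: without it the log2 fold change was 0.54 in place of 1.36. The split was 1255 up and 5432 down on the deposited FPKM scale, where the median log2 fold change of all genes was -0.21 in place of -0.02, and 3713 up and 2152 down after the length and GC correction. Of 39 lists, 21 were called with the preset correlation and 0 with an estimated one.

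**Figure D5:**
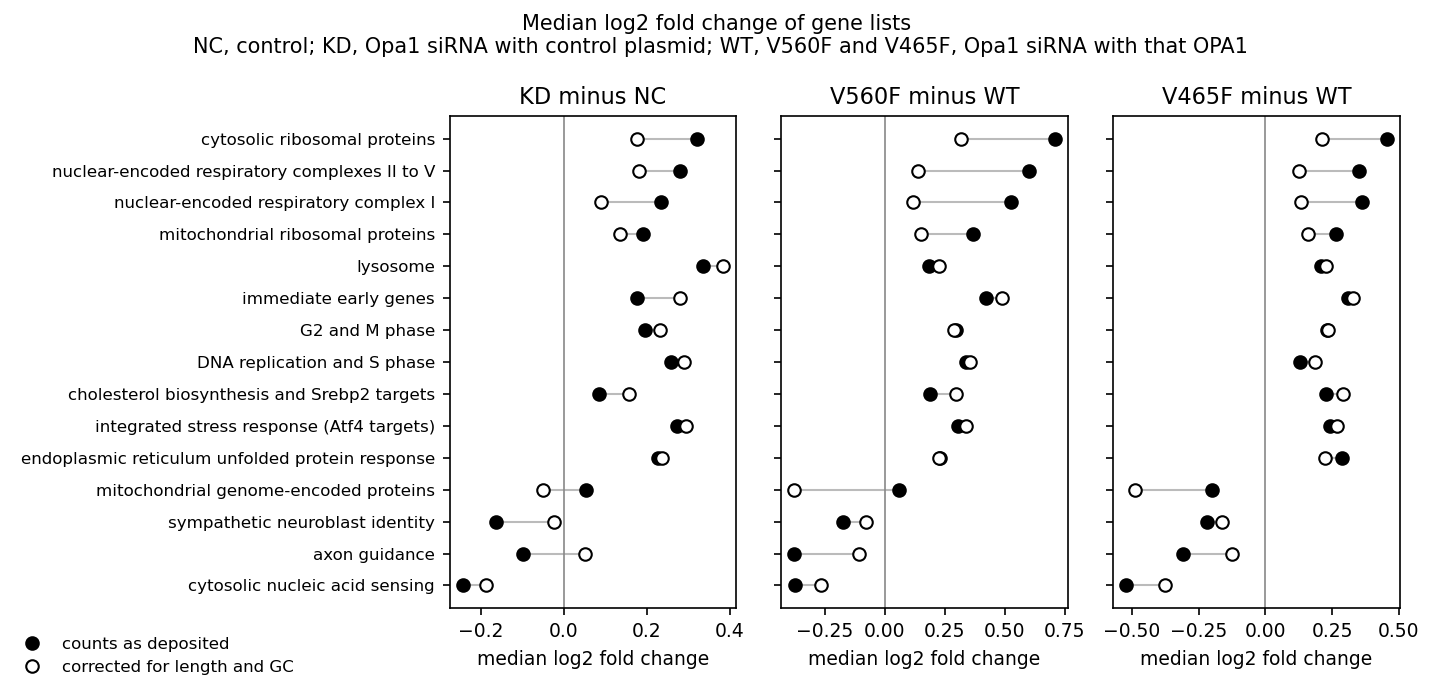
Median log2 fold change of 15 gene lists in the knockdown (KD minus NC), V560F and V465F comparisons (each minus WT), from the counts as deposited (filled) and after correction for transcript length and GC content (open). The cytosolic ribosomal protein list moves from 0.71 to 0.32 in V560F, while the G2 and M phase list is at 0.30 and 0.29.

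The fourth comparison sets V465F against wild-type OPA1. Immediate early, ribosomal, respiratory chain, lysosomal and G2 and M phase genes were higher on balance, and of axon guidance, sympathetic lineage and nucleic acid sensing genes more fell than rose. Fos rose 2.40-fold to 22.4 ± 5.23 CPM and Egr1 2.32-fold to 170.0 ± 22.3 CPM. Nfkbia rose 1.88-fold to 190.9 ± 11.6 CPM and Irf1 1.54-fold (edgeR adjusted p = 9.36e-07, 4.80e-09, 1.62e-07 and 3.26e-06 for the 4 genes). Of the 30 immediate early genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median log2 fold change of 0.31 as deposited and 0.33 corrected (camera adjusted p = 7.84e-06, adjusted p = 0.334 with an estimated correlation). All 74 cytosolic ribosomal protein genes rose, and 74 adjusted over the list alone, with a median of 0.45 that was 0.21 after the correction (camera adjusted p = 5.43e-26, adjusted p = 0.334 with an estimated correlation). Respiratory complex I genes rose in 32 of 37 cases (34 adjusted over the list alone) and genes of complexes II to V in 33 of 39 (34 adjusted over the list alone). Their medians were 0.36 and 0.35, and 0.13 for both after the correction (camera adjusted p = 3.97e-10 and 1.52e-11, adjusted p = 0.334 for both with an estimated correlation).

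Lysosomal genes rose in 20 of 33 cases and fell in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 1.12e-05, adjusted p = 0.288 with an estimated correlation). The sialidase gene Neu1 rose by 0.53 ± 0.0828 and Tfeb, a regulator of lysosomal genes, fell by 0.67 ± 0.120 on the log2 scale. Cholesterol biosynthesis genes rose in 12 of 24 and fell in 2 (13 and 2 adjusted over the list alone), with Fdft1 at 0.42 ± 0.0642 and Idi1 at 0.41 ± 0.0645 (camera adjusted p = 3.96e-05, adjusted p = 0.334 with an estimated correlation; median reversed to -0.00302, adjusted p = 0.835, with quantile normalization). Of 40 integrated stress response genes 22 rose and 6 fell (22 and 8 adjusted over the list alone), with Ddit3 at 0.67 ± 0.0956 and Chac1, which degrades glutathione, at 0.61 ± 0.0983 (camera adjusted p = 0.000484, adjusted p = 0.334 with an estimated correlation). In the unfolded protein response of the endoplasmic reticulum 16 of 27 rose and 4 fell (16 and 5 adjusted over the list alone), with Calr up by 0.52 ± 0.0675 and the stress sensor gene Eif2ak3 down by 0.59 ± 0.0764 on the log2 scale (camera adjusted p = 0.000894, adjusted p = 0.334 with an estimated correlation). G2 and M phase genes rose in 21 of 37 (24 up and 1 down adjusted over the list alone), with Top2a at 0.52 ± 0.0671 and Ccna2 at 0.44 ± 0.0580 (camera adjusted p = 2.96e-07, adjusted p = 0.288 with an estimated correlation).

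Some sympathetic lineage genes fell with V465F, Gata2 by 0.63 ± 0.0797 and Hand2 by 0.43 ± 0.0678 (edgeR adjusted p = 6.48e-06 and 5.65e-05). In that list 4 of 19 fell and 0 rose by the edgeR test, with the same numbers adjusted over the list alone. The camera adjusted p was 0.00596, and 0.288 with an estimated correlation. Of all 13074 tested genes 2621 fell and 2367 rose, so the share of the list that fell was near that of all genes. Sema6d fell by 1.21 ± 0.140, Sema6a by 1.12 ± 0.143 and Unc5c by 0.83 ± 0.120. Of 31 axon guidance genes 12 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.00596, adjusted p = 0.334 with an estimated correlation). This call was lost after the length and GC correction (camera adjusted p = 0.132). Among 10 nucleic acid sensing genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), including Adar (-0.89 ± 0.0962) and Ddx58 (-0.66 ± 0.102) (camera adjusted p = 0.0278, adjusted p = 0.322 with an estimated correlation). Of the 13 proteins of mitochondrial DNA, 4 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.383). CYTB fell by 0.32 ± 0.0670 and COX1 rose by 0.32 ± 0.0685, and 9 were lower and 1 higher after the correction (camera adjusted p = 1.14e-05, adjusted p = 0.268 with an estimated correlation). Among the genes that maintain and express that DNA, Twnk fell by 0.99 ± 0.126, Tfam by 0.42 ± 0.0759 and Tefm by 1.42 ± 0.301 on the log2 scale, with 2 of 22 higher and 7 lower (3 and 7 adjusted over the list alone; camera adjusted p = 0.125).

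Bmf fell 3.51-fold, from 11.4 ± 0.876 to 3.25 ± 0.232 CPM (edgeR adjusted p = 1.64e-08), and Bbc3 rose by 0.44 ± 0.0999. Of 24 pro-apoptotic genes 3 rose and 4 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.440). In the fusion, fission and cristae list 14 of 36 rose and 8 fell (14 and 8 adjusted over the list alone; camera adjusted p = 0.0996), with Mfn2 down by 0.36 ± 0.0719 and Chchd3 up by 0.43 ± 0.0728. In all, 4988 genes changed, 2367 up and 2621 down, of which 72 rose and 271 fell by at least 2-fold (edgeR adjusted p under 0.05). These 343 were 17, 11, 12 and 39 in the same 4 settings and 203 after the length and GC correction. The largest named falls included Zfp455 (3.79-fold), Thap2 (3.49-fold, from 12.4 ± 1.56 to 3.57 ± 0.677 CPM) and Glcci1 (3.25-fold), and the largest rises Akr1b7 (3.47-fold) and H1f2 (2.23-fold). Rnaset2b, at 5.90 ± 6.53 CPM with V465F, passed the test at a log2 fold change of 2.03 because of V465F replicate 2, without which it was 0.57 (edgeR adjusted p = 0.163). It has a close paralog and overlaps another gene on its strand. The split was 989 up and 4133 down on the deposited FPKM scale and 3219 up and 1797 down after the length and GC correction. Of 39 lists, 22 were called with the preset correlation and 0 with an estimated one.

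The fifth comparison sets the mutants against each other, as the series ties their effects to different domains of OPA1. Slbp, which binds the stem-loop of histone messenger RNA, was the 1 gene called, at 51.4 ± 2.18 CPM with V465F and 71.8 ± 4.48 CPM with V560F (log2 fold change -0.48 ± 0.0704, edgeR adjusted p = 0.00889). It overlaps a gene on the opposite strand. Without V560F replicate 3, V465F replicate 1 or V465F replicate 2, Slbp was at -0.47, -0.47 and -0.46 with edgeR adjusted p = 0.0575, 0.129 and 0.134, and 0 genes were called by edgeR in each of these fits. Other genes missed the threshold, among them Wars (0.49 ± 0.1, edgeR adjusted p = 0.0909), Lonp1, a protease of the mitochondrial matrix (0.31 ± 0.0647, edgeR adjusted p = 0.107), and Junb (-0.44 ± 0.112, edgeR adjusted p = 0.127). After the length and GC correction Wars, Lonp1 and Junb were called, at 0.49, 0.31 and -0.36 (edgeR adjusted p = 0.0241, 0.0212 and 0.049). An unadjusted p under 0.05 was met by 2373 genes, and DESeq2 called 147 and limma on FPKM 6. The edgeR test called 818 genes without V560F replicate 1 and 580 with no filter on low counts, so the count of 1 depends on the libraries and on the settings. Cytosolic ribosomal protein genes had a median log2 fold change of -0.26, corrected -0.10, with 0 called over all genes by edgeR and 72 of 74 lower adjusted over the list alone (camera adjusted p = 4.11e-25, adjusted p = 0.692 with an estimated correlation). DNA replication genes had a median of -0.17, corrected -0.14, with 1 lower over all genes and 10 of 37 lower adjusted over the list alone (camera adjusted p = 1.20e-07, adjusted p = 0.185 with an estimated correlation). Axon guidance genes had a median of 0.12, corrected 0.05 (camera adjusted p = 0.00171, adjusted p = 0.692 with an estimated correlation), with 0 of 31 called over all genes or adjusted over the list alone by edgeR. The median 95% interval of ±0.228 on the log2 scale limits how small a difference between the mutants could be seen.

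Set against the knockdown group itself, both mutants changed more genes than against wild-type OPA1. V560F changed 7040 genes, 3432 up and 3608 down, and V465F changed 6015, 2867 up and 3148 down (edgeR adjusted p under 0.05), of which 153 and 103 rose and 571 and 384 fell by at least 2-fold. These 724 and 487 were 43 and 24 with quantile normalization. Fos was 3.11-fold higher with V560F and 2.58-fold higher with V465F, and Egr1 was 2.54-fold and 2.65-fold higher (edgeR adjusted p = 1.19e-08, 2.09e-07, 6.47e-10 and 2.88e-10). Bmf, at 11.8 ± 0.170 CPM in the knockdown libraries, was 3.32-fold lower with V560F and 3.62-fold lower with V465F. Glcci1 was 3.997-fold and 3.18-fold lower, and Fbxl7 3.72-fold and 2.82-fold lower. Pomc, the precursor of melanocortin peptides, rose from 0.936 ± 0.228 to 2.90 ± 1.01 and 2.47 ± 0.477 CPM. Cholesterol biosynthesis genes rose in 18 of 24 cases with V560F and 19 of 24 with V465F, with 1 lower in each (18 up and 2 down, and 20 up and 1 down, adjusted over the list alone; camera adjusted p = 7.66e-06 and 2.29e-08, adjusted p = 0.336 and 0.329 with an estimated correlation; for V560F the median reversed to -0.00608, adjusted p = 0.777, with quantile normalization). Immediate early genes rose in 19 of 30 in both, with 1 lower in each and the same adjusted over the list alone (camera adjusted p = 1.09e-07 and 1.38e-07, adjusted p = 0.278 and 0.311 with an estimated correlation). On the deposited FPKM scale the splits were 1496 up and 5613 down for V560F and 1410 up and 4574 down for V465F, and after the length and GC correction 3836 up and 2307 down, and 3512 up and 2157 down.

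The overlap of the mutants' changes was tested directly. Of the genes called against wild type, 2135 rose with both mutants and 2233 fell with both, with 0 in opposite directions by edgeR. Independent lists of those sizes would share 580 and 653.5. Egr1, Fos, Nfkbia and Irf1 were among those higher with both, and Bmf, Glcci1 and Adar among those lower with both. The log2 fold changes of the mutants correlated across genes with Pearson r = 0.802, where 100 simulations of unchanged groups sharing the wild-type libraries gave a mean r of 0.454. Their covariance was 0.185 against a simulated 0.0216. Against the knockdown libraries 2556 rose with both and 2686 fell with both (752.6 and 868.7 for independent lists), with r = 0.834 against a simulated 0.462 and a covariance of 0.232 against 0.0224. Genes are not independent replicates, and because 3 shared libraries cannot be divided into separate sets of at least 2, part of the excess may come from the shared controls. The simulated groups also held no trend with transcript length. Fold changes fell with length in both mutants (Spearman rho -0.444 for V560F and -0.353 for V465F against wild type, -0.485 and -0.401 against knockdown). The simulations therefore do not show how much of the excess comes from that shared trend. The knockdown and wild-type re-expression comparisons, which share the knockdown libraries, had r = -0.168 where simulation gave -0.509, and a covariance of -0.0183 against -0.0223.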

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

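The fit on FPKM with a pseudocount of 1, the length and GC correction, the restriction to genes with both values, the removal of the 2 farthest libraries or of the 50 most abundant genes, and thinning were chosen after the data were seen; the other alternatives were planned. The fall of Opa1 after knockdown kept its direction and its side of the threshold in every alternative run, with log2 fold changes of -1.42 to -1.32 when 1 library was left out. The number of genes called stayed within 1.5 times the reported number in 5 comparisons, except for 2606 in the knockdown with the filter of 5 FPKM, which tested fewer genes. With 1 library left out the edgeR numbers were 3235 to 4151 for knockdown, 5381 to 6451 for V560F and 3634 to 4945 for V465F against wild type, and 6272 to 6981 and 4868 to 5480 against knockdown. For wild-type OPA1 they were 0 in each of the 6 fits, while 40 genes were called by edgeR with no filter, 3 with only the 6 libraries, 43 with array weights, 5 with DESeq2 and 2 without the farthest libraries. Ucp2 was among them with no filter, with only the 6 libraries, with array weights and without the farthest libraries, at log2 fold changes of 0.38, 0.38, 0.42 and 0.42 (adjusted p = 0.0013, 0.0374, 0.0189 and 0.0237). For V465F against V560F the reported 1 gene became 6 with each of the FPKM pseudocounts, 2 with quantile normalization, 580 with no filter, 7 with the filter of 5 FPKM, 0 with only the 6 libraries, 3 with a replicate block and 3 with robust moderation, 2 with array weights, 147 with DESeq2, 72 with the length and GC correction, 17 without the farthest libraries and 2 after thinning. It was 0 to 818 with 1 library left out, 818 of them without V560F replicate 1. The cause was not tested. The replicate block gave 4676, 0, 6446, 4995, 3, 7066 and 6025 genes in the order of the comparisons. Residuals of libraries with the same number correlated at -0.179 to 0.0878, so numbers were not taken as pairs. In the order of the comparisons, 6, 6, 1, 3, 2, 4 and 6 of the 6 libraries correlated best with the library of their own number. A weak pairing by number is therefore not excluded.

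Numbers of genes with a change of at least 2-fold moved more. In the order knockdown, V560F and V465F against wild type, and V560F and V465F against knockdown, they were 409, 559, 343, 724 and 487 as reported. They became 26, 78, 17, 127 and 35 with FPKM and a pseudocount of 1, and 61, 195, 63, 312 and 121 with 0.5. With median-ratio scaling they were 18, 30, 11, 45 and 21 and with quantile normalization 16, 28, 12, 43 and 24, both also with a pseudocount of 1. With the filter of 5 FPKM, in the edgeR test, they were 23, 115, 39, 153 and 76. Most of the reported numbers thus rested on genes below that filter. In the knockdown a pseudocount of 0.1 gave 182, so the number fell as the pseudocount rose. The length and GC correction gave 323, 203, 397 and 296 in the other 4. Why the remaining settings moved the numbers was not tested. For wild-type OPA1, with 0 by edgeR, there were 5 with no filter and 1 with array weights. For V465F against V560F, also with 0 by edgeR, there were 17 with no filter, 1 each with DESeq2, the length and GC correction and the farthest libraries left out, and 0 to 16 with 1 library left out, 16 of them without V560F replicate 1. With 1 library left out the others were 324 to 450, 443 to 690, 258 to 392, 596 to 876 and 386 to 551.

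Of the 39 lists, 0 were called by camera with an estimated correlation in each of the 7 comparisons. Quantile normalization gave 5 called lists in the knockdown in place of 16, 9 for wild-type OPA1 in place of 16, 11 for V465F against wild type in place of 22, and 11 and 7 for V560F and V465F against knockdown in place of 21 and 20. The filter of 5 FPKM gave 10 in the knockdown, the FPKM fits with each pseudocount gave 13 in place of 21 for V560F against wild type, and the length and GC correction gave 10 for wild-type OPA1 and 4 for V465F against V560F in place of 10. In that last comparison 6 were called without the farthest libraries. Leaving out 1 library gave 13 to 16, 10 to 17, 20 to 23, 21 to 22, 6 to 12, 19 to 21 and 19 to 21 lists in the order of the comparisons, with 10 for wild-type OPA1 without wild-type replicate 1 and 6 for V465F against V560F without V560F replicate 2. Quantile normalization also reversed the direction of 5 list results. For V560F against wild type the medians became -0.0575 for the integrated stress response, -0.118 for cholesterol biosynthesis and -0.039 for lysosome, and cholesterol biosynthesis became -0.00302 for V465F against wild type and -0.00608 for V560F against knockdown, with none of these called. The cause was not tested. Genes shared by the knockdown and wild-type comparisons in the same direction, 0 as reported by edgeR, numbered 10 with no filter, 13 with array weights and 2 with DESeq2. Over all alternatives, 3355 of 3402 values of the 144 named gene results kept their direction and side of the threshold, as did 1404 of 1487 values of the 62 named list results. With the filter of 5 FPKM no epithelial marker was left to test.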

Other observations

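The tests of Opa1 depth in the mutant libraries and of abundant genes, both tests on the wild-type comparison and the choice of gene ontology terms were made after the results were seen; the other tests were written before. Most genes of a translation initiation complex, and part of those of the spliceosome, rose in the knockdown and in both mutants. Of the 15 genes of the translation initiation factor 3 complex, 14 rose in the knockdown, 12 with V560F and 11 with V465F against wild type (camera adjusted p = 1.98e-05, 5.40e-07 and 9.01e-06 over 2095 terms; 0.000134, 0.000105 and 0.000173 after the length and GC correction; 0.602, 0.565 and 0.687 with an estimated correlation), and Eif3c was at 0.56 ± 0.0589, 0.53 ± 0.0588 and 0.49 ± 0.0588 on the log2 scale. Of 155 spliceosome genes 65, 91 and 63 rose and 5, 17 and 16 fell (camera adjusted p = 4.33e-05, 2.15e-07 and 0.000179; 0.671, 0.565 and 0.698 with an estimated correlation), with Hnrnph1 at 0.74 ± 0.0808 for V560F and 0.57 ± 0.0807 for V465F. Of 96 G protein-coupled receptor genes 27, 39 and 29 fell and 9, 3 and 2 rose (camera adjusted p = 0.0104, 0.000783 and 0.00447; 0.602, 0.565 and 0.687 with an estimated correlation), and the cannabinoid receptor gene Cnr1 was at -1.15 ± 0.0982, -1.11 ± 0.108 and -0.90 ± 0.105. With an estimated correlation 0 of the 2095 terms were called by camera in each comparison. Fold changes rose with expression level in these comparisons (Spearman rho 0.416, 0.236 and 0.229), which the length and GC correction does not model. How far that trend moves these terms was not tested.

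For other terms the knockdown and the mutants had different calls, and the difference between the knockdown and either mutant's comparison was not tested. Of 16 genes of the response to bone morphogenetic proteins, 2 fell and 2 rose in the knockdown, while 12 fell with V560F, 10 fell with V465F and 0 rose with either by edgeR (camera adjusted p = 0.807, 0.00141 and 0.000419; adjusted p = 0.923, 0.565 and 0.687 with an estimated correlation). The receptor gene Bmpr1a was at -0.53 ± 0.0728 and -0.45 ± 0.0724 with the mutants and the signal mediator gene Smad1 at -0.70 ± 0.0837 and -0.50 ± 0.0822. Of 26 genes of the neuronal action potential 8 fell in the knockdown, among them Cntnap2 (-2.25 ± 0.336) and the sodium channel gene Scn2a (-0.53 ± 0.107), 7 fell and 1 rose with V560F, and 0 fell and 1 rose with V465F by edgeR. The median log2 fold changes were -0.283, -0.282 and -0.0912 (camera adjusted p = 0.00806, 0.209 and 0.881; adjusted p = 0.619, 0.634 and 0.951 with an estimated correlation). Tested directly, V465F lay above V560F for this term (camera adjusted p = 0.00293; 0.667 with an estimated correlation and 0.181 after the length and GC correction). After that correction the knockdown was still called (camera adjusted p = 0.0176), and V560F and V465F were at 0.846 and 0.894, with V465F upward. The corrected values of Scn2a were -0.4382 in the knockdown and -0.1508 for V560F, against -0.3926 for V560F before the correction.

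The genes called for the mutants against wild type were weighed against 3 technical explanations. After the correction for transcript length and GC content, 68.5% of the V560F calls and 73.0% of the V465F calls were still called in the same direction, which argues against the trend as the whole source of either set. At equal library totals 96.2% and 94.8% were, which argues against depth. If a few abundant genes took the counts of the others, the others would fall together on FPKM divided by the table total. On that scale 1216 and 957 genes other than the 50 most abundant were called higher, which argues against those genes as the whole source, while 5432 and 4133 were called lower, with median log2 fold changes of all genes of -0.207 and -0.137, so a part of the falls on that scale may come from them. Leaving out the 50 genes moved the median of all genes by 0.0009 and 0.0017, since TMM trims such genes, and so decides nothing. The trend may still account for part of the change in groups of short genes, as for respiratory complex I, whose median for V560F went from 0.53 to 0.12. RNA quality and handling of the groups were not recorded, so a batch that follows the groups cannot be separated from the plasmid. Libraries had 17184 to 17532 genes detected in control, 16737 to 16992 in knockdown and wild type, and 15984 to 16175 in the mutants. At near-equal totals of 22186086 and 22188334 counts, control replicate 1 had 17184 genes detected and V465F replicate 3 had 16089. The cause of this difference, and its part in the falls of at least 2-fold, was not tested.

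The changes of the mutants against wild type followed the direction of the knockdown, with which they share no library. Of the genes called in both, 1753 rose and 1188 fell in the knockdown and with V560F (636.9 and 521.1 for independent lists), while 137 and 43 went opposite ways, and for V465F these numbers were 1374 and 913 (470.5 and 419) with 143 and 40 opposite. The fold changes correlated at r = 0.509 and 0.454, and at 0.489 and 0.419 after the length and GC correction, which argues against that trend as the whole source. Fold changes also rose with expression level in the knockdown, V560F and V465F comparisons (Spearman rho 0.416, 0.236 and 0.229). The correction did not model that trend, and its part in the correlation was not tested. Opa1 in the mutant libraries differed from wild type by 0.0277 and 0.111 on the log2 scale, upward, but these counts may mix plasmid and mouse RNA, so a deeper knockdown of the mouse gene stays open. A stronger loss of OPA1 function with either mutant is a hypothesis that these values also leave open, as are differences in delivery or culture between the groups, which no value here tests. Measuring OPA1 protein and inner membrane fusion in the same 5 groups, with mouse and plasmid transcripts counted apart, would decide it.

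No gene was called by edgeR for wild-type OPA1 against the knockdown (1157 at an unadjusted p under 0.05; DESeq2 called 5, edgeR 40 with no filter, 3 with only the 6 libraries and 2 without the farthest libraries, and the fit with array weights 43). Another comparison of the same fit and size called 7040 genes, but the Benjamini-Hochberg adjustment is more lenient where many genes differ. That number therefore does not measure the power here. In simulated data for this comparison, with 200 genes changed, 46 of 50 genes changed by 2-fold were recovered. This argues against too few libraries or reads for large changes. Small changes may have been missed, since 17 of 50 simulated genes with 1 group 25% above the other were recovered here. Opa1 was at -0.229 on the log2 scale, but it is not known whether plasmid RNA was counted as Opa1. A plasmid that was not expressed therefore cannot be told apart from one that was expressed and changed little. Nor was it tested whether the knockdown's changes come from loss of Opa1 or from other effects of the siRNA. For each comparison the 6 libraries can be split 10 ways, too few for a share under 0.05. The real split called 4689, 0, 6464, 4988, 1, 7040 and 6015 genes in the order of the comparisons, where the highest other split called 0, 0, 0, 0, 1, 0 and 0 by edgeR. As many genes as the real split came from 1, 10, 1, 1, 2, 1 and 1 of the 10 splits, the real one included.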
